A study of Cereibacter sphaeroides with 9 samples.

How the data were processed

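RNA sequencing of 9 libraries of *Rhodobacter sphaeroides* 2.4.1 was analysed: 3 of the wild type without plasmid, 3 of the strain with pRK4352_RSP_6037 and 3 of the strain with pRK4352_CcsR1-4. Per the labels' protocols, total RNA was extracted with hot phenol, treated with DNase I and made into Illumina libraries. Groups and replicate numbers were taken from the labels. The WT titles carry the word old, whose meaning is not given, and the titles of the strains carry a tag for 32 °C that the WT titles lack, so a separate batch for WT can be neither seen nor excluded from the labels.

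The authors deposited 2 tables, 1 for each strain against WT, with 4411 features on the sense strand. Per the file headers, each holds counts per library with the authors' mean level, log2 fold change, p-value and adjusted p-value for each feature. The WT counts were identical in both tables, with 0 differing values. The deposited counts are estimated counts: whole numbers, within 1e-06, made up 7.01% to 14.0% of the values of a library. Per the submitters' processing notes, Trim Galore 0.6.3, DESeq and DESeq2 1.22.1 were used by the authors, in roles that are not given. The aligner, the counting tool, the genome build and the treatment of reads that match several places are not given in the sources used here. Genes with near-identical copies may therefore share reads, and the values of paralogues, such as the chemotaxis, complex I and cold-shock protein genes, are uncertain to that extent. The authors' mean level exceeded the count of every library for 564 features, so it was not used. The features were 4280 protein-coding genes, 54 tRNA, 9 rRNA, 67 small RNA and 1 tmRNA features on 7 replicons. Coordinates are those of the tables. Gene symbols are those of the tables, and the reference table of gene names was not used here. Some named genes, such as sitA, sitB, sitC and sitD, overlap a neighbour on the same strand, and their values are uncertain to the extent that reads are shared. No antisense features were used here, so the antisense share planned in advance was not computed.

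Fold changes, tests and lists were computed here from the counts. rRNA and tRNA features were left out of library sizes and tests, which left 4348 features. A feature was tested where at least 3 libraries reached the CPM that 10 counts give at the median library size, and it had at least 15 counts in all, which kept 3807. CPM are counts per 1000000 of the counts outside rRNA and tRNA, after scaling by the trimmed mean of M values (trimming 30% of fold changes and 5% of levels, own implementation). limma 3.58.1 in R 4.3.3 fitted the 3 group means over all 9 libraries to log2 values from voom, which adds 0.5 to each count, and moderated the variances with 11.7 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all tested features, with a threshold of 0.05. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

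The test fixed before the data were examined, edgeR's quasi-likelihood F test, was not used. The deposited values carry decimal commas, which kept the columns from being recognised as counts under the rules set for the work, and count-model packages were then ruled out. The reason for limma-voom is thus the number format and not the nature of the values. The other choices of test, threshold, comparisons, word patterns of the gene lists and naming rule were made before the data were examined. Members of some lists were left out later, once the product names had been seen.

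On simulated data with 200 changed genes, drawn from the levels and library sizes of these samples with a dispersion of 0.00632, the fit over 3755 genes recovered 86.6% of the genes changed by a log2 fold change of 1 and 98.8% of those changed by 2 in OE_RSP_6037 against WT, with 4.48% false discoveries. For OE_CcsR1-4 against WT it recovered 86.8% and 99.0%, with 4.18%. The simulated spread is that of counts with 1 dispersion for all genes, so the recovered shares are upper guides. The shares of false discoveries may be higher in the data. Far fewer genes were changed in the simulation than were called in the data against WT (1177 and 1245).

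The 25 gene lists were defined as word patterns in the product names and tested by camera with a preset correlation of 0.01, and again with an estimated one, for lists of at least 3 tested genes. Members of some lists, such as ATP synthase, complex I and ribosomal proteins, are neighbours on the same strand and may be transcribed together. Counts of list members are therefore not counts of independent changes. Patterns for 10 lists also took unrelated products, such as ABC transporters under ATP synthase. These were left out after the product names had been seen and before any fold change was computed, and the lists as matched are an alternative. Library shares were compared by exact permutation tests, two-sided.

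The genes named are RSP_6037 and the small RNAs of its locus; the 10 largest increases and 10 largest decreases against WT among called genes whose 3 strain libraries all lay on the same side of the 3 WT libraries, and the 5 largest each way between the strains; up to 4 members with the smallest adjusted p of each list past its test; and rpoE1, chrR, rpoH1, rpoH2, flhR, hfq and rne. Chosen after their values were seen were RSspA01, RSP_3094, sitB, sitC, sitD, RSP_1951, pgi, RSP_2365, RSP_0579 and RSP_4160, the 8 genes called in opposite directions, and the runs of neighbouring genes in the closing section.

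Alternatives were median-of-ratios size factors, no low-count filter, rRNA and tRNA kept, the replicate number as a block, fits of the 6 libraries compared, each library left out, an estimated list correlation, limma-trend, scaling without the trimmed mean, scaling to all counts and the lists as matched. The last 4 were chosen after seeing the data. For the comparison of both strains with the shared WT libraries, unchanged groups were simulated 100 times. The covariance of the fold changes was also computed with each strain set against another single WT library. The strain libraries were also thinned to the mean WT depth of 684638 counts. Chi-square values per degree of freedom between replicates of a group were 2.06 to 4.64, so no libraries were duplicates.

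The authors' deposited tables call 467 features for OE_RSP_6037 and 539 for OE_CcsR1-4 outside rRNA and tRNA at an adjusted p under 0.05. Of these, 463 and 535 were tested here, and all were called here in the same direction. The calls made here are more numerous, 1177 and 1245, so most of them are not called in the authors' deposited tables. The authors' deposited log2 fold changes and those computed here had r = 0.996 across genes in both comparisons.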

Results

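Total RNA was sequenced from *Rhodobacter sphaeroides* 2.4.1, a purple bacterium of flexible metabolism, in 3 groups of 3 libraries. The wild type (WT) carried no plasmid. The strain OE_RSP_6037 carried pRK4352_RSP_6037, from which RSP_6037, a small protein with a DUF1127 domain, is expressed constitutively. The strain OE_CcsR1-4 carried pRK4352_CcsR1-4, from which the small RNAs CcsR1 to CcsR4 are expressed constitutively. In the genome these small RNAs follow RSP_6037 on the same strand. All cultures grew exponentially in malate minimal medium at 32 °C in the dark, with 25 µM dissolved oxygen and shaking at 140 rpm. The labels call the libraries triplicates without saying that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The libraries held 9112946 to 12913573 counts each. Outside rRNA and tRNA the WT libraries held 602271 to 760103 counts and the plasmid strains 1272563 to 1462002, so WT values carry the larger counting error.

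The composition of total RNA differed between the groups. 16S rRNA, the RNA of the small ribosomal subunit, made up 20.4% ± 0.708 (SD, n = 3) of all counts in WT, 13.4% ± 0.721 in OE_RSP_6037 and 10.9% ± 1.19 in OE_CcsR1-4. 23S rRNA moved less, with 51.5% ± 1.25 in WT, 48.5% ± 0.315 in OE_RSP_6037 and 47.8% ± 1.52 in OE_CcsR1-4. The ratio of 16S to 23S counts was 0.396 ± 0.0224 in WT, 0.276 ± 0.0144 in OE_RSP_6037 and 0.228 ± 0.0194 in OE_CcsR1-4. Protein-coding genes took 4.82% ± 0.274 of the counts in WT, 9.43% ± 0.317 in OE_RSP_6037 and 10.7% ± 1.2 in OE_CcsR1-4. tRNA took 17.3% ± 0.853, 19.8% ± 1.25 and 21.5% ± 1.58, in the same order. For the 16S share, and for the ratio, each pair of groups gave p = 0.1 (exact permutation test, two-sided), the smallest p that 3 against 3 libraries can give, so this design cannot reach 0.05. The coding share of the plasmid strains overlapped (exact permutation test, p = 0.2). All fold changes that follow are relative to the other mRNAs and small RNAs: scaled to all counts, rRNA and tRNA included, the median gene lay 0.93 higher in OE_RSP_6037 and 1.17 higher in OE_CcsR1-4 than in WT on the log2 scale, and every list median given as lower than WT then lay above 0.

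**Figure D1:**
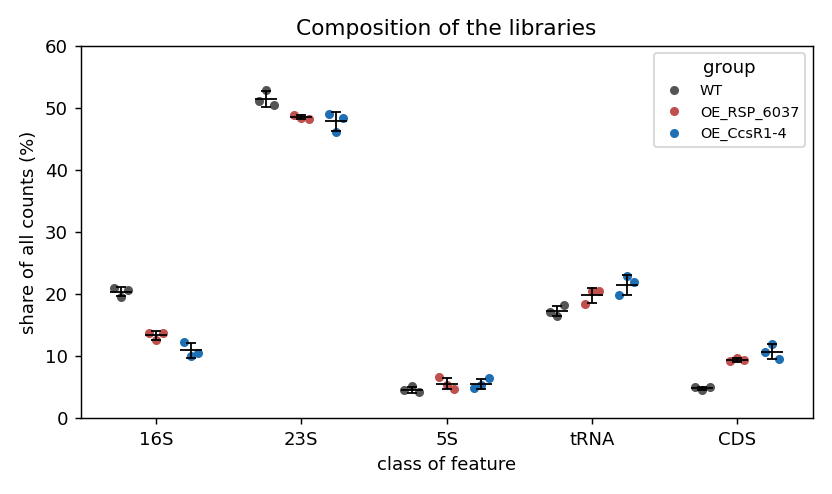
Share of all counts, in percent, taken by 16S, 23S and 5S rRNA, tRNA and protein-coding genes (CDS) in each library; points are libraries, bars the mean and SD of 3. The 16S shares of the 6 plasmid libraries reach at most 13.8%, below the WT mean of 20.4%.

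RSP_6037 (chromosome 1, 692457 to 692672, minus strand, coding sequence) stood at 464 ± 105 counts per 1000000 (CPM; SD, n = 3) in WT, at 4060.2 ± 198 in OE_RSP_6037 and at 1330.2 ± 87.0 in OE_CcsR1-4. It rose 8.91-fold in OE_RSP_6037 (log2 3.16, SE 0.12, limma-voom adjusted p = 2.0e-12). RSP_6037 also rose 2.92-fold in OE_CcsR1-4 (log2 1.54, SE 0.12, limma-voom adjusted p = 1.6e-08).

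The tables hold 3 features of the small RNAs, RSs0680a (692372 to 692455), RSs0680b (692272 to 692348) and RSs0680c (692157 to 692240). RSs0680a stood at 6786 ± 659 CPM in WT, 6187 ± 874 in OE_RSP_6037 and 20898 ± 5718 in OE_CcsR1-4, a rise of 3.02-fold in the last (log2 1.59, SE 0.14). RSs0680b rose 3.18-fold (log2 1.67, SE 0.11) and RSs0680c 2.64-fold (log2 1.40, SE 0.10) in OE_CcsR1-4. In OE_RSP_6037 the log2 fold changes were -0.14 for RSs0680a (limma-voom adjusted p = 0.49), 0.10 for RSs0680b (0.54) and 0.06 for RSs0680c (0.74), none past the threshold. As a list, RSP_6037 and these 3 small RNAs stood apart from the other genes in OE_CcsR1-4 (camera adjusted p = 2.4e-06, 0.081 with an estimated correlation), with 4 of 4 members higher, and 4 of 4 adjusted over the list alone. The plasmid of this strain expresses these small RNAs, so the list checks the construct and tests no response. No feature was matched to RSs0680d, which was not analysed here.

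**Figure D2:**
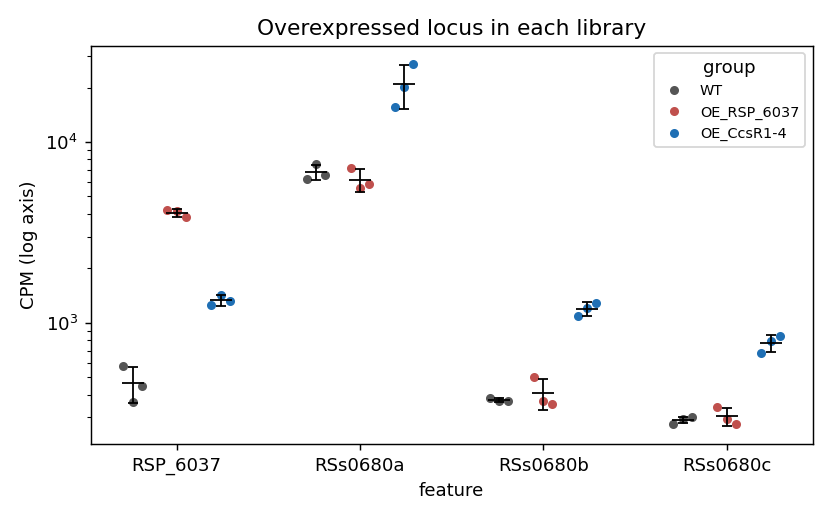
CPM of RSP_6037 and of the small RNA features RSs0680a, RSs0680b and RSs0680c in each library, on a log axis; points are libraries, bars the mean and SD of 3. RSP_6037 is raised in both plasmid strains and the small RNAs in OE_CcsR1-4 alone of the 2 strains.

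The comparison of OE_RSP_6037 with WT asks which transcripts differ when the small protein is expressed from a plasmid. Beside RSP_6037, envA, which encodes the deacetylase of lipid A synthesis, rose 6.88-fold (log2 2.78, SE 0.10, limma-voom adjusted p = 2.0e-12), from 713 ± 113 to 4871 ± 255 CPM. The 4 neighbours RSP_3386 to RSP_3389, for a TRAP-type transporter and enzymes annotated as tartrate or isocitrate dehydrogenases, rose by log2 2.25 to 2.79. The gene deoD of purine nucleoside phosphorylase fell to 0.169 times its WT level (log2 -2.57, SE 0.13, limma-voom adjusted p = 2.6e-10), from 380.1 ± 39.9 to 63.8 ± 10.3 CPM. The cold-shock protein gene RSP_3620 fell from 516 ± 9.24 to 105 ± 8.86 CPM (log2 -2.30, SE 0.12).

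Other large rises in OE_RSP_6037 were expE1, of an RTX calcium-binding protein (log2 2.47), the sigma factor gene RSP_3095 (log2 2.02) and RSP_2363, of a short-chain dehydrogenase (log2 2.27). RSP_3094, next to RSP_3095 and annotated as a putative anti-sigma factor, rose too (log2 1.79). RSP_1471 went from 1.91 ± 0.788 to 12.9 ± 4.03 CPM, with counts too low for a firm fold. Among the large falls were RSP_7617 (log2 -2.66), RSP_3622 of a DUF982 protein (log2 -2.31), the hemin uptake protein gene RSP_6006 (log2 -2.46) and pgl, of 6-phosphogluconolactonase in the oxidative pentose phosphate pathway (log2 -2.51). RSP_6082 (15.6 ± 6.05 to 2.42 ± 1.47 CPM), RSP_3469 (15.7 ± 8.58 to 3.68 ± 2.42), RSP_3794 (17.7 ± 5.76 to 4.35 ± 3.01) and proW(RSP_3999), of a glycine betaine transporter (6.77 ± 1.99 to 1.14 ± 0.683), fell as well, at low counts.

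In OE_RSP_6037, 26 of 54 tested ribosomal protein genes fell, 3 rose and 25 did not pass the test (camera adjusted p = 2.7e-05, 0.22 with an estimated correlation). Adjusted over the list alone, 28 fell and 3 rose. Examples were rpsU (log2 -1.52), rplR (-0.71), rplL (-0.64) and rpsN (-0.62). Of 61 genes of flagella and chemotaxis, 18 fell and 3 rose, the same counts as adjusted over the list alone (camera adjusted p = 0.0030, 0.22 with an estimated correlation). flhA of the flagellar export gate (log2 -1.39), the chemotaxis kinase gene cheA4 (-1.87), mcpG (-1.57) and flgK1 (-1.06) were among them.

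Of 26 genes of complex I, the proton-pumping NADH dehydrogenase, 11 fell and 3 rose in OE_RSP_6037, with 12 and 3 adjusted over the list alone (camera adjusted p = 0.015, 0.41 with an estimated correlation). nuoG fell by 0.93, nuoK by 0.85, nuoM by 0.64 and nuoL by 0.47 on the log2 scale. The runs nuoG to nuoI and nuoJ to nuoN, of 4 and 5 neighbours on the same strand, were lower together. Of 8 genes of iron-sulfur cluster assembly, 6 fell and none rose, with 7 falling adjusted over the list alone (camera adjusted p = 0.0060, 0.22 with an estimated correlation). They included sufB (log2 -0.39), the cysteine desulfurase gene RSP_0431 (-0.41), rdxB (-0.42) and RSP_1143 (-0.75). rdxB is annotated as a cluster-binding protein and RSP_1143 as a ferredoxin, neither an assembly factor. The call for RSP_1143 ended without WT replicate 3 (log2 -0.59, limma-voom adjusted p = 0.053).

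Of 25 genes named for RNA turnover, 11 fell and 3 rose in OE_RSP_6037, as also adjusted over the list alone (camera adjusted p = 0.016, 0.37 with an estimated correlation). The members with the smallest adjusted p were cold-shock proteins, which bind RNA and single-stranded DNA, and not ribonucleases: RSP_3620, RSP_3621 (log2 -1.51), RSP_1952 (-1.56) and RSP_0386 (-0.78). With 7 deoxyribonuclease genes that the search pattern had also taken, the list missed the threshold (camera adjusted p = 0.098). The ATP synthase list, with 4 of 14 genes lower, lay at the threshold without passing it (camera adjusted p = 0.0502), and passed with the replicate number as a block (0.043); without the trimmed-mean scaling 7 genes were lower.

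In all, 1177 of 3807 tested features differed between OE_RSP_6037 and WT, 620 higher and 557 lower (limma-voom, adjusted p under 0.05), and 185 of them by at least 2-fold, 82 higher and 103 lower. Without the trimmed-mean scaling, 463 were higher and 750 lower, and scaled to all counts 3198 were higher and 36 lower. No list call held with a correlation estimated from the data. Libraries with the empty plasmid were not analysed here, so against WT the insert cannot be told apart from plasmid carriage, and the 16S to 23S ratio was lower in the same libraries (0.276 against 0.396).

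The comparison of OE_CcsR1-4 with WT asks the same of the small RNAs. Here envA rose 4.68-fold (log2 2.23, SE 0.10, limma-voom adjusted p = 1.3e-10) and expE1 5.87-fold (log2 2.55, SE 0.19, limma-voom adjusted p = 1.6e-08). The genes sitA, sitB, sitC and sitD of a manganese and iron importer rose by log2 1.97, 1.82, 1.75 and 1.54, with sitA going from 508 ± 154 to 1922 ± 226 CPM. The same genes rose in OE_RSP_6037, by 1.38 to 1.60, and none of them passed the test between the strains, although sitB did in the fit of those 6 libraries alone (log2 -0.33, limma-voom adjusted p = 0.041). All 14 tested ATP synthase genes fell, by a median of 0.60 on the log2 scale. deoD fell to 0.186 times its WT level (log2 -2.43, SE 0.13) and RSP_3620 to 0.176 times (log2 -2.51, SE 0.13).

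Further rises in OE_CcsR1-4 were RSP_3387 (4.52-fold), RSP_3388 (3.99-fold), the nucleoside diphosphate kinase regulator gene rnk (4.01-fold), RSP_4255 of a mechanosensitive channel (3.81-fold), RSP_7522 (3.77-fold) and RSP_2360, annotated as a phage portal protein (3.81-fold). RSP_6245, a phage protein gene, went from 1.5 ± 2.06 CPM in WT to 16.4 ± 5.02. Further falls were RSP_7617 (log2 -2.84), RSP_3622 (-2.28), RSP_6138 (-2.40), RSP_4246 (-2.25) and RSP_0919 (-2.19). RSP_2472 (13.4 ± 4.39 to 2.02 ± 2.55 CPM), RSP_3794 (17.7 ± 5.76 to 4.13 ± 3.92) and RSP_4150 (10.8 ± 0.529 to 2.18 ± 0.177) fell at low counts.

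The fall of the ATP synthase list in OE_CcsR1-4 passed its test (14 of 14 lower, also adjusted over the list alone; camera adjusted p = 9.6e-08, 0.074 with an estimated correlation). atpI fell by 0.66, atpG by 0.64, atpA(RSP_2297) by 0.62 and atpD(RSP_2299) by 0.52. The runs atpH to atpC and atpF to atpI, each of 5 neighbours on the same strand, were lower together. With 55 ABC transporter genes that the search pattern had also taken, the list did not stand apart (camera adjusted p = 0.34). Of 26 complex I genes 12 fell and none rose, 13 adjusted over the list alone (camera adjusted p = 1.7e-04, 0.17 with an estimated correlation). Examples were nuoK (log2 -0.96), nuoG (-0.92), nuoM (-0.67) and nuoH (-0.64). The run from nuoH to nuoN, of 8 neighbours on the same strand, was lower together.

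Of 15 genes of the terminal oxidases and the bc1 complex, 8 fell and none rose in OE_CcsR1-4, as also adjusted over the list alone (camera adjusted p = 0.0011, 0.074 with an estimated correlation). The genes ccoN (log2 -0.64), ccoO (-0.57), ccoP (-0.51) and ccoQ (-0.70) of the cbb3 oxidase, used at low oxygen, were among them. Of 15 genes of the tricarboxylic acid cycle, 9 fell and none rose, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.0014, 0.074 with an estimated correlation). They included mdh (log2 -0.81), ttdA (-1.40), sucC (-0.68) and sdhB (-0.62). RSP_3386 to RSP_3389, which were higher in this strain, are not among the 15. The tricarboxylic acid cycle list as its pattern matched also passed (camera adjusted p = 0.0095).

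Ribosomal protein genes in OE_CcsR1-4 gave 23 falls and 4 rises among 54, with 24 and 4 adjusted over the list alone (camera adjusted p = 1.7e-04, 0.17 with an estimated correlation), among them rpsU (log2 -1.34), rplR (-0.77), rplL (-0.70) and rplJ (-0.68). The RNA turnover list had 10 falls and 2 rises among 25, with 11 and 3 adjusted over the list alone (camera adjusted p = 0.0011, 0.17 with an estimated correlation), again led by the cold-shock genes RSP_3620, RSP_1952 (log2 -1.77), RSP_3621 (-1.32) and RSP_0386 (-0.85). Iron-sulfur cluster assembly had 5 falls and no rise among 8, with 6 falls adjusted over the list alone (camera adjusted p = 0.0072, 0.096 with an estimated correlation), among them rdxB (log2 -0.58), sufB (-0.45), RSP_0431 (-0.33) and RSP_1143 (-0.66).

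The 16S to 23S ratio was lower in these libraries as well (0.228 against 0.396 in WT). In all, 1245 of 3807 features differed between OE_CcsR1-4 and WT, 630 higher and 615 lower (limma-voom, adjusted p under 0.05), and 229 by at least 2-fold, 100 higher and 129 lower. Scaled to all counts, 3486 were higher and 20 lower. The call for RSP_1143 ended without WT replicate 2 or 3 or without OE_CcsR1-4 replicate 1, with log2 values of -0.49 to -0.60 (limma-voom adjusted p = 0.054 to 0.093).

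Of 7 regulators named in advance, 4 passed the test in both comparisons. The anti-sigma factor gene chrR rose by log2 0.77 in OE_RSP_6037 and 0.46 in OE_CcsR1-4, the latter not past the threshold without WT replicate 3 (0.43, limma-voom adjusted p = 0.067). The gene rpoH1 of a heat-shock sigma factor rose by 0.51 and 0.60, and rpoH2, of its paralogue, fell by 0.55 and 0.65. flhR, of a response regulator, rose by 0.56 and 0.45. The authors' deposited tables call flhR in OE_RSP_6037 (adjusted p = 0.016) but not in OE_CcsR1-4 (0.066), and do not call chrR (0.22 and 0.54), rpoH1 (0.33 and 0.23) or rpoH2 (0.60 and 0.51). The sigma factor gene rpoE1 (log2 0.28 and 0.00), hfq of the RNA chaperone (0.20 and 0.02) and rne of RNase E in OE_RSP_6037 (-0.16) did not pass. In OE_RSP_6037, rpoE1 passed without WT replicate 3 (0.42) or OE_RSP_6037 replicate 3 (0.40), and hfq without the latter (0.28); rne passed there without the trimmed-mean scaling (-0.25, limma-voom adjusted p = 0.023). rne fell by 0.21 in OE_CcsR1-4 at a limma-voom adjusted p of 0.045, a call lost in 8 of the alternative fits, among them those without WT replicate 2 (-0.21) or 3 (-0.17) or without any of the OE_CcsR1-4 libraries (-0.17 to -0.22).

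Both strains moved alike against WT. The same direction was called in both comparisons for 873 features, 460 higher and 413 lower, where independent lists of these sizes would share 102.6 and 90.0, and for 8 features the directions were opposite. Across the 3807 genes, which are not independent replicates, the log2 fold changes had r = 0.81 (Spearman's rho 0.81) and a covariance of 0.213. Unchanged groups simulated against the same WT libraries gave r = 0.61, rho = 0.57 and a covariance of 0.0259, and shared at most 2 calls. They hold no changed genes, so few calls could be shared, and that count is no measure for the 873. Groups with separate changes in each strain were not simulated. The 3 WT libraries cannot be split into parts of at least 2 each, so part of the excess in r and shared calls may come from the shared controls.

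**Figure D3:**
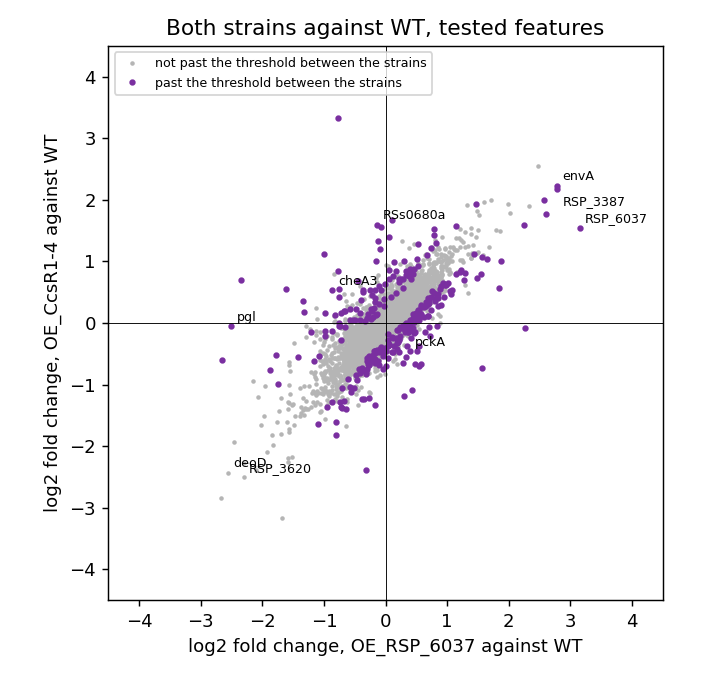
Log2 fold change of each tested feature against WT in OE_RSP_6037 (x axis) and OE_CcsR1-4 (y axis); purple points passed the threshold between the strains. Most of the 3807 points lie along the diagonal (r = 0.81), with envA and RSP_3387 high and deoD low in both strains.

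The comparison of OE_RSP_6037 with OE_CcsR1-4 is free of the difference in plasmid backbone, but not of one in RNA composition: the 16S to 23S ratio (0.276 and 0.228) and the rRNA share (67.5% and 64.3%) did not overlap between the strains. RSP_6037 was 3.05-fold higher in OE_RSP_6037 (log2 1.61, SE 0.11, limma-voom adjusted p = 5.1e-08). RSs0680a, RSs0680b and RSs0680c were lower, by log2 -1.73, -1.56 and -1.34. RSP_2363 (log2 2.35), the aldolase gene fucA (2.29) and the sugar transporter genes RSP_2365 (1.49) and RSP_2367 (1.51) were higher in OE_RSP_6037, while pgl (-2.45), zwf (-1.17) and pgi (-1.52), of glucose 6-phosphate metabolism, were lower. pgl stood at 9.08 ± 1.53 CPM in OE_RSP_6037, against 51.4 ± 6.83 in OE_CcsR1-4 and 53.9 ± 10.2 in WT.

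RSP_6138 was also higher in OE_RSP_6037 than in OE_CcsR1-4 (log2 2.07). RSP_6245 (0.589 ± 0.244 against 16.4 ± 5.02 CPM), proW(RSP_3999) (1.14 ± 0.683 against 11.3 ± 1.36), cheB2 (3.42 ± 2.41 against 14.4 ± 4.21) and slp (3.78 ± 1.39 against 16.8 ± 1.67) were lower, at low counts. Of 61 flagella and chemotaxis genes, 6 were lower and none higher, with 9 lower adjusted over the list alone (camera adjusted p = 4.6e-04, 0.11 with an estimated correlation), among them cheA3 (log2 -1.40), cheW4 (-1.62) and cheA4 (-1.11). Without the trimmed mean 9 were lower, and scaled to all counts 15, with a list median of -0.43, from -0.21. In the main fit the run from cheA3 to cheB2, of 6 neighbours on the same strand, was lower together. The call for cheA4 ended without OE_RSP_6037 replicate 1 or 2 or OE_CcsR1-4 replicate 1 or 2 (log2 -0.91 to -1.05, limma-voom adjusted p = 0.068 to 0.099).

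Of 14 ATP synthase genes, 10 were higher in OE_RSP_6037 than in OE_CcsR1-4 and none lower, with 13 higher adjusted over the list alone (camera adjusted p = 5.7e-10, 0.054 with an estimated correlation, and 0.81 for the list as its pattern matched). atpG (log2 0.50), atpX (0.45), atpI (0.38) and atpH (0.34) were among them. The runs atpH to atpC and atpF to atpI, each of 5 neighbours on the same strand, were higher together. Of 15 tricarboxylic acid cycle genes 6 were higher and none lower, as also adjusted over the list alone (camera adjusted p = 4.7e-04, 0.065 with an estimated correlation), including sdhB (0.50), sdhA(RSP_0976) (0.33), RSP_0975 (0.40) and mdh (0.38). These counts depend on the scaling: without the trimmed mean 5 ATP synthase genes and 2 of the tricarboxylic acid cycle were higher, and scaled to all counts 0 and 0, with list medians of 0.13, from 0.36, and 0.06, from 0.29. The calls for sdhB (0.44) and mdh (0.31) ended without OE_CcsR1-4 replicate 3, and that for RSP_0975 without OE_CcsR1-4 replicate 3 or OE_RSP_6037 replicate 1 or 2 (0.28 to 0.39). The calls for sdhA(RSP_0976) (0.25) and RSP_0975 (0.32) ended without the trimmed-mean scaling.

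Of 15 oxidase and bc1 genes 2 were higher, qxtB (log2 0.39) and ccoO (0.27), as also adjusted over the list alone (camera adjusted p = 0.016, 0.12 with an estimated correlation). Of 7 genes of the 2-oxoacid dehydrogenases 2 were higher, sucA (0.30) and sucB (0.26), and 3 adjusted over the list alone (camera adjusted p = 0.036, 0.16 with an estimated correlation), while pdhAa (0.23) and RSP_0962 (0.12) did not pass. Without the trimmed mean 1 of the oxidase genes and 0 of the dehydrogenase genes were higher. Scaled to all counts, 0 were, and the list medians became -0.03 for the oxidases, from 0.19, and -0.12 for the dehydrogenases, from 0.12. Leaving out a single library ended the calls for qxtB (OE_CcsR1-4 replicate 2, log2 0.34), ccoO (OE_RSP_6037 replicate 2 or 3 or any OE_CcsR1-4 library, 0.25 to 0.28), sucA (OE_RSP_6037 replicate 2 or OE_CcsR1-4 replicate 1 or 2, 0.28 to 0.29) and sucB (OE_RSP_6037 replicate 2 or 3 or any OE_CcsR1-4 library, 0.22 to 0.29). Those for ccoO (0.19), sucA (0.22) and sucB (0.18) ended without the trimmed mean too, and that for sucB also with limma-trend (limma adjusted p = 0.072), with rRNA and tRNA kept and with no low-count filter (limma-voom adjusted p = 0.055). The locus list, with RSP_6037 higher and the 3 small RNAs lower, differed as well (4 of 4 adjusted over the list alone, camera adjusted p = 4.7e-04, 0.16 with an estimated correlation). The plasmids express different members of this list, so its outcome was set by the constructs.

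In all, 289 features differed between the strains, 187 higher and 102 lower in OE_RSP_6037 (limma-voom, adjusted p under 0.05), 36 of them by at least 2-fold, 12 higher and 24 lower. Without the trimmed-mean scaling 110 were higher and 198 lower, and without OE_RSP_6037 replicate 2 the count was 173. Scaled to all counts, 38 were higher and 489 lower.

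**Figure D4:**
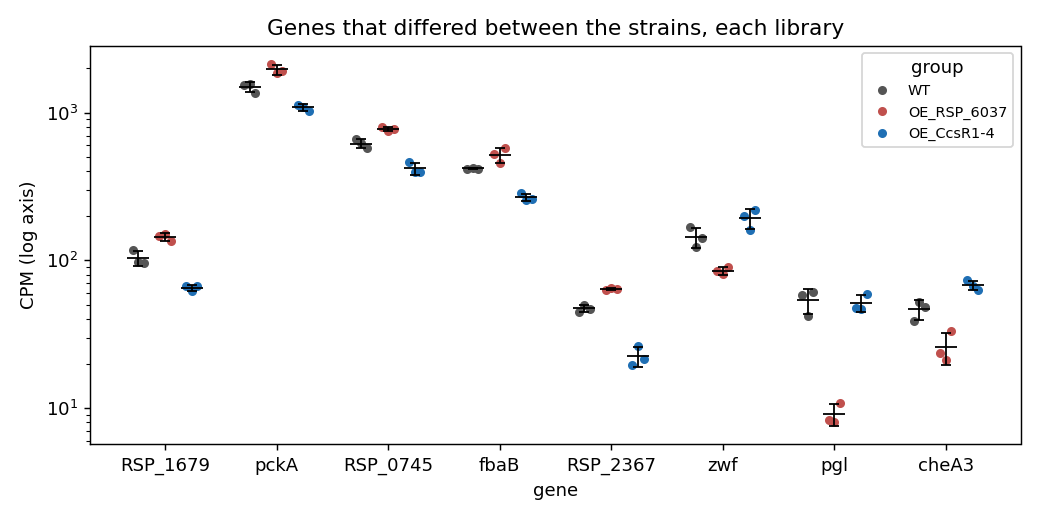
CPM of 8 genes in each library, on a log axis; points are libraries, bars the mean and SD of 3. The genes pckA, fbaB, RSP_1679, RSP_0745 and RSP_2367 lie highest in OE_RSP_6037 and lowest in OE_CcsR1-4, and zwf and cheA3 the other way round; pgl is low in OE_RSP_6037 alone.

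**Figure D5:**
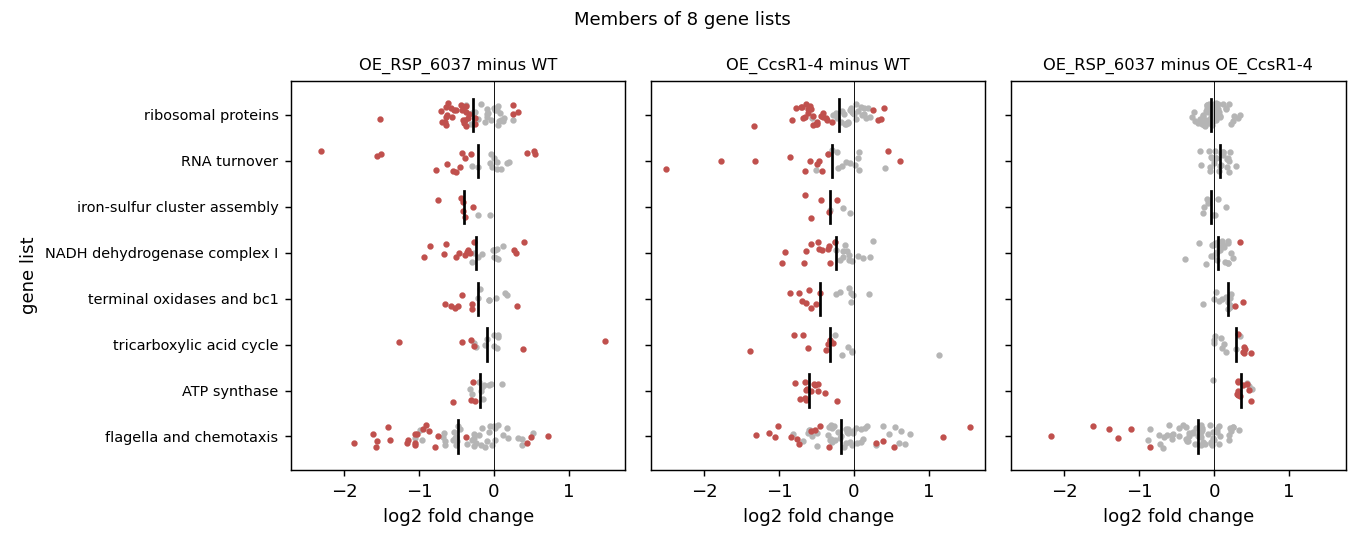
Log2 fold change of the tested members of 8 gene lists in the 3 comparisons; each point is a gene, red where it passed the threshold, and the bar is the list median. The ATP synthase genes fall in OE_CcsR1-4, with a median of -0.60, more than in OE_RSP_6037, with a median of -0.19.

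The remaining lists did not pass camera in any comparison. The values that follow are for OE_RSP_6037 and then OE_CcsR1-4 against WT, over the tested members. Chaperones and proteases had 9 of 27 and 7 of 27 genes higher, and 2 and 1 lower (camera adjusted p = 0.095 and 0.60). Sigma factors had 5 of 15 higher and 2 lower in both (0.25 and 0.20). Oxidative stress and thiol defence had 7 of 49 higher in both and 6 and 9 lower (0.94 and 0.73). Photosynthesis had 13 and 16 of 43 higher and 11 and 12 lower (0.86 and 0.73). Small RNAs had 14 of 57 higher in both and 10 and 15 lower (0.29 and 0.78). Translation factors and tRNA ligases had 3 of 36 higher in both and 10 and 11 lower (0.095 and 0.20). Iron uptake had 7 of 33 higher in both and 4 and 6 lower (0.82 and 0.78). Without the trimmed mean the counts in OE_RSP_6037 became 7 higher and 14 lower for photosynthesis, with a median of -0.02, from 0.07, 5 and 10 for oxidative stress and thiol defence, and 7 and 8 for iron uptake.

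Among the smaller lists against WT, C1 compound oxidation had 2 of 16 higher and 1 lower in both strains (camera adjusted p = 0.82 and 0.78). Tetrapyrrole synthesis had 1 and 2 of 12 higher and 2 and 0 lower (0.62 and 0.73), the Calvin cycle 1 of 6 higher and 1 and 4 lower (0.62 and 0.38), and nitrogen fixation 2 of 9 higher (0.78 and 0.74). Polyhydroxyalkanoate storage had 1 of 4 higher (0.78 and 0.65), sulfate and cysteine assimilation 2 and 1 of 12 higher and 3 and 2 lower (0.94 and 0.84), and transposases and integrases 2 and 4 of 24 lower (0.22 and 0.37), the former 6 without the trimmed mean. The DUF1127 list held RSP_6037 alone and was not tested. In OE_RSP_6037 the oxidases (7 of 15 lower, 0.055), the tricarboxylic acid cycle (4 lower, 0.29), the 2-oxoacid dehydrogenases (0.97) and the locus (0.19) did not pass, nor did flagella and chemotaxis in OE_CcsR1-4 (11 of 61 lower, 5 higher, 0.37) or the dehydrogenases there (0.37).

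By replicon, genes of plasmid B lay lowest against WT, with a median log2 fold change over 13 genes of -1.03 in OE_RSP_6037 and -0.89 in OE_CcsR1-4, and -0.04 between the strains. Of these genes 7 and 6 fell. With 1 library left out, 14 to 18 genes of plasmid B were tested, so some lay near the low-count filter. A gene could pass that filter through the libraries of 1 group alone. Plasmid D, with 89 genes, had medians of -0.24 and -0.27, with 28 and 35 genes lower. The medians of chromosome 1 (2826 genes) were 0.00 and -0.00, and those of chromosome 2 (693 genes) -0.06 and -0.03. Plasmids A, C and E had medians between -0.07 and 0.06.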

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

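The 8 genes given here were called against WT in opposite directions in the strains. These genes were selected by their calls after the fits were made. The comparison of the strains with each other called each of them too, but its value is the difference of the other 2 values in the same fit, so calls in opposite directions nearly fix its outcome and it adds no separate test. The authors' deposited tables call none of the 8 genes in both comparisons: RSP_1679, fbaB and RSP_2367 are called in OE_CcsR1-4 (adjusted p = 0.020, 4.3e-04 and 0.0016), cheA3 in OE_RSP_6037 (0.036), and pckA, RSP_0745, RSP_2370 and zwf in neither. Chance enters both WT comparisons through the same 3 libraries.

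Higher than WT in OE_RSP_6037 and lower than WT in OE_CcsR1-4 were 6 genes. RSP_1679, of methylsuccinyl-CoA dehydrogenase in the ethylmalonyl-CoA pathway, had log2 fold changes of 0.48 and -0.67, a difference of 1.14. Its neighbour pckA, of phosphoenolpyruvate carboxykinase, had 0.40 and -0.46, a difference of 0.85, with 1961 ± 151 CPM (SD, n = 3) in OE_RSP_6037, 1490.0 ± 112 in WT and 1086 ± 53.0 in OE_CcsR1-4. RSP_0745, of acetyl-CoA acetyltransferase, had 0.33 and -0.56, a difference of 0.89. fbaB, of fructose-bisphosphate aldolase, had 0.29 and -0.65, a difference of 0.94. The sugar transporter gene RSP_2367 had 0.43 and -1.08, a difference of 1.51, and the sugar kinase gene RSP_2370 had 0.58 and -0.66, a difference of 1.24.

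Lower than WT in OE_RSP_6037 and higher in OE_CcsR1-4 were 2 genes. zwf, of glucose-6-phosphate dehydrogenase, had log2 fold changes of -0.75 and 0.42, a difference of -1.17. cheA3, of a chemotaxis kinase, had -0.86 and 0.53, a difference of -1.40.

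All 8 differences between the strains passed in each alternative fit run for them, but 4 of the calls against WT did not. RSP_2367 in OE_RSP_6037 missed the threshold without any 1 of the 6 libraries compared (log2 0.40 to 0.47) with the replicate block (limma-voom adjusted p = 0.059), with limma-trend (0.058) and without the trimmed mean (0.12); over all its alternatives the adjusted p ran from 0.042 to 0.12. fbaB in OE_RSP_6037 missed it without WT replicate 2 (0.30) or 3 (0.29) or OE_RSP_6037 replicate 3 (0.21), or without the trimmed mean (0.21). zwf in OE_CcsR1-4 missed it without WT replicate 2 (0.30) or 3 (0.42) or OE_CcsR1-4 replicate 1 (0.40) or 3 (0.34). cheA3 in OE_CcsR1-4 missed it without WT replicate 1 (0.42) or 3 (0.57) or OE_CcsR1-4 replicate 1 (0.49).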

How the results depend on the processing

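Limma-trend, scaling without the trimmed mean, scaling to all counts, the lists as their patterns matched, the 2-fold counts with rRNA and tRNA kept and the ranges for the 16S share were chosen after seeing the data; the other alternatives were planned. The planned DESeq2 alternative was not run, for the reason given for the main test. Counts of changed genes stayed within 1.5 times under median-of-ratios size factors, no low-count filter, rRNA and tRNA kept, fits of 6 libraries, limma-trend and scaling without the trimmed mean. Scaled to all counts, they were 3234 in OE_RSP_6037 against WT, 1632 of them 2-fold, 3506 in OE_CcsR1-4, 2522 of them 2-fold, and 527 between the strains, since the median gene then moved with the rRNA share. Leaving out each library gave 924 to 1061, 940 to 1072 and, between the strains, 173 (without OE_RSP_6037 replicate 2) to 248, with 189 to 202 and 216 to 229 changed 2-fold. Fewer libraries lower the power. Same-numbered libraries of different groups had residual correlations of -0.0280 to 0.0697 over 9 pairs. These lie below the 0.1 used as the threshold for pairing, so the samples were not treated as paired. A weak pairing is not excluded. With the replicate number as a block the counts were 1225, 1311 and 324, and the list tests passed 6, 8 and 6 lists. With an estimated correlation, 0 lists passed in each of the 3 comparisons, against 5, 8 and 6 with the preset one. The 8 and the 6 include the locus list, which the plasmids were built to change. A correlation above the preset 0.01 does not account for every lost call. In OE_CcsR1-4 the estimates were below it for iron-sulfur cluster assembly (-0.0075), the oxidases (-0.0055) and the tricarboxylic acid cycle (-0.039). For ribosomal proteins (0.062) and ATP synthase (0.075) there, among others, they were above it. What else ended the calls was not tested. The lists as matched passed 4, 7 and 5. The correlation of the strains' fold changes was 0.619 without the genes called in either comparison, which removes the largest changes; unchanged groups gave 0.610 on average and 0.657 at most over all genes, so this r alone does not show a shared response among the genes left. Their covariance was 0.0509, and 74.4% had the same sign in both strains. Over all tested genes, the unchanged groups gave a covariance of 0.0259 on average and 0.0298 at most, and 70.8% with the same sign on average. The unchanged groups were not limited to the genes left, so these values do not decide on a shared response among them.

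Of the genes named, 59 of 67, 68 of 76 and 43 of 55 kept direction and side of the threshold in every alternative run for them. In these alternatives signs turned only for values that had not passed. Scaling to all counts was not run for single named genes, and there calls against WT turned: the ATP synthase list in OE_CcsR1-4 went from 14 genes lower to 12 higher and 0 lower, and complex I from 12 lower to 24 higher and 0 lower. RSs0680b in OE_RSP_6037 ranged from -0.0457 to 0.198 when 1 library was left out, and RSs0680c from -0.0300 to 0.129, with -0.0289 without the trimmed mean. rpoE1 in OE_CcsR1-4 was -0.00736 with limma-trend, -0.00475 without the trimmed mean and -0.00265 in the fit of 6 libraries, and ranged from -0.103 to 0.135 with 1 library left out. hfq there ranged from -0.0137 to 0.0718, and RSP_0579 from -0.114 to 0.0601. Between the strains rne was -0.0336 without the trimmed mean and ranged from -0.00269 to 0.0759. The cause was not tested.

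Replicon medians with 1 library left out ranged, for OE_RSP_6037 against WT, from -0.00500 to 0.00984 on chromosome 1, from -1.32 to -0.955 on plasmid B and from -0.170 to -0.0200 on plasmid E. For OE_CcsR1-4 they ranged from -0.00255 to 0.0239 on chromosome 1, from 0.0123 to 0.138 on plasmid C, from -0.329 to -0.205 on plasmid D and from -0.0691 to 0.126 on plasmid E. Between the strains plasmid E ranged from -0.148 to -0.0390. The difference in 16S share from WT ranged from -7.40 to -6.59 points in OE_RSP_6037 and from -10.1 to -9.02 in OE_CcsR1-4. The cause was not tested. With 602271 to 760103 counts outside rRNA and tRNA, depth limits the WT values of genes near the filter most; thinned to the mean WT depth, the fits called 1001, 1048 and 187 genes.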

Other observations

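Of the tests in this part, the 1 on a response graded with the level of RSP_6037 was set down before its result was seen; the others, and the runs of neighbouring genes, were chosen after the results were seen.

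Genes for photosynthesis moved apart within their list. The run pufM, pufL, pufA, pufB and pufK, of the reaction centre and its antenna, was lower in both strains, with a median log2 fold change of -0.79 in OE_RSP_6037 and -1.12 in OE_CcsR1-4. The run bchF, bchN, bchB and bchH of bacteriochlorophyll synthesis was higher, with medians of 0.41 and 0.69. Runs that end at cobL, of cobalamin synthesis, were higher by 0.94 (6 genes from cobW) and 0.83 (7 genes from RSP_2829), and the run ivdH, mccB, mccA, hmgL and RSP_2511 of leucine breakdown by 0.71 and 0.34. A run of 12 genes from RSP_2351 to RSP_2360, which includes the phage portal protein gene, was higher in OE_CcsR1-4 by 0.90, and its 4 genes RSP_2357 to RSP_2360 were also higher in OE_RSP_6037, by a median of 1.06. The small RNA RSspA01 was the most abundant feature outside rRNA and tRNA in each of the 6 plasmid libraries and rose 2.31-fold and 2.02-fold, from 28870.4 ± 4622 CPM (SD, n = 3) in WT. RSP_1951, of a DUF982 protein beside the cold-shock gene RSP_1952, changed by log2 -1.92 and -2.10.

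Between the strains, 10 runs of at least 4 neighbours passed the threshold together, 8 higher and 2 lower in OE_RSP_6037. The run from RSP_2362 to RSP_2371, of sugar transport and use, was higher by a median of 1.24, and 7 genes of plasmid D around RSP_4160 by 0.86. The run from cheA3 to cheB2 was lower, with a median of -1.66, and that from RSP_0575 to RSP_0579, which includes acetyl-coenzyme A synthetase, with -0.94.

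The first pattern is the response that both plasmid strains shared against WT. Error of single WT libraries, or the lower depth of WT, does not give it alone. The covariance of the fold changes was 0.213. With each strain set against another single WT library, so that no error of a single library was shared, it was at least 0.177. The covariance was at least 0.180 when the strain libraries were also thinned to the mean WT depth. An error common to all WT libraries would remain in both settings. Of the 873 shared genes, 45.4% moved further in OE_RSP_6037, although that strain holds more RSP_6037. This argues against a response that grows with RSP_6037 as the only source. It cannot exclude a part that does, since other contributions to the same genes may hide it. The study's own inserts, plasmid carriage and a separate WT batch may each contribute and cannot be told apart, since 0 libraries with an empty vector, or of WT with the strains' title tag, were among the 9.

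The second pattern is the rise of RSP_6037 in OE_CcsR1-4. A rise of the whole native locus in any plasmid strain is argued against by the small RNAs in OE_RSP_6037, whose median log2 fold change was 0.0576. Reads of the insert could account for it if the insert reaches into RSP_6037: the features lie 1 base apart, and RSP_6037 gained 6.14% of the CPM that RSs0680a gained. The ends of the insert and the position of each read would help to decide, and neither was used here. This therefore cannot be told apart from a rise of the native transcript in that strain.

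The third pattern is the lower 16S share. Dilution by other RNA would lower 16S and 23S alike, but the ratio reached at most 0.286 in the 6 plasmid libraries, below the lowest WT value of 0.370. Reads moved between copies of the gene are argued against by the summed 16S share, which reached at most 13.8%, below the lowest WT share of 19.6%. RNA quality or library preparation of a WT batch could account for it and cannot be told apart from the plasmid or the inserts, since 0 WT libraries carry the strains' title tag.

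Other splits of the 6 libraries of each comparison, tested by limma-voom, gave 0 changed genes at most, in place of 1122, 1196 and 329, and 0 changed 2-fold, in place of 170 and 217. At an unadjusted p under 0.05 they gave at most 84, 85 and 245 genes, in place of 1468, 1556 and 798. In list tests the other splits passed up to 3, 6 and 3 lists, in place of 5, 8 and 6. Each of these other splits leaves part of the group difference, with 2 libraries of a group on one side and 1 on the other. Leaving aside the counts at an unadjusted p, 8 counts of genes or lists remain. In each of these, 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.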
